A study of Mus musculus with 18 samples.

How the data were processed

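PolyA RNA from whole kidney of 18 mice was sequenced, 6 animals each of wild-type C57BL/6J, Dp16 and Dp16^2xIFNRs, with 3 males and 3 females per group. Per the labels' protocols, RNA was extracted with TRIzol, strand-specific libraries were made with a Tecan/NuGEN Universal Plus mRNA kit, and paired-end reads were taken on an Illumina NovaSeq instrument. Per the submitters' processing notes, the tools were bcl2fastq, FastQC 0.11.5, HISAT2 2.1.0, SAMtools 1.5 and HTSeq 0.6.1 with build GRCm38. The strand setting of the counting step is not stated there.

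The authors deposited raw counts per gene for 55385 genes, with no normalization. The authors also deposited RPKM values for the same genes, and how these were made is not stated. Dividing counts by RPKM gave a gene length equal in all samples within 0.1% in 15255 of 15255 genes checked, with the sample's total count as the denominator. Library totals were 42157790 to 57814587 counts, mitochondrial genes took 6.34% to 10.88% and the 10 highest genes 11.97% to 16.18% of each library. No pair of libraries was a duplicate (lowest chi-square per degree of freedom 19.99). Coordinates came from GENCODE M21 (GRCm38), in which 55144 of the 55385 identifiers were found, and 8 genes placed on chromosome 16 had no position. The segment was taken as chromosome 16 from 75540514 to 97962622 (22.4 Mb), from Lipi to Zbtb21, which holds 384 genes of the tables, 115 of them tested.

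Genes were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 in 1 fit of all 18 libraries, with group and sex as terms and TMM normalization. The filter kept genes by group with a minimum count of 10 and a minimum total of 15, which left 17575 genes and removed 37810. P values were two-sided and adjusted by Benjamini-Hochberg, with 0.05 as the threshold. The SE of a log2 fold is the fold's size divided by the square root of its F statistic and is approximate. The biological coefficient of variation was 16.8%. Means of lists were taken over log2 CPM with a prior count of 2. Differences in such means were tested by permuting animals within sex, all 400 ways, with a 95% interval from inverting the test, and 0.005 is the smallest p this gives. Interactions of sex and genotype were tested in an edgeR fit with both terms and their product.

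The 36 gene lists of pathways and cell types, the comparisons, the tests, the alternatives and the rule for named genes were fixed before the data were examined. Genes of the segment were left out of every list. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation, with fry, and by permutation. For Dp16 against wild-type camera called 17 lists, of which 6 held with an estimated correlation. For Dp16^2xIFNRs against wild-type it called 19, and 0 held with an estimated correlation, while fry called 13 and the permutation 10. For Dp16^2xIFNRs against Dp16 it called 6, and 0 held with an estimated correlation, in fry or by permutation, with 11 under an unadjusted camera p of 0.05.

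The rule for named genes took, per comparison, the 4 receptor genes and the 6 largest rises and 6 largest falls outside the segment among called genes with an average log2 CPM of at least 0. It added the 5 called segment genes of smallest p, the 3 highest-expressed segment genes not called, and the 3 members of smallest p of each list with a call. It also took up to 5 interaction genes and the genes that check sex. The coat colour gene nonagouti and its neighbours were added after their values were seen. Some genes that the rule takes are not reported.

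Alternatives were RLE size factors, no filter on low counts, a filter at an average log2 CPM of 1, no sex covariate, age as a covariate, the sample number as a block, DESeq2 1.42.0, fits of 2 groups alone, the last description number as a random block in limma-voom, limma-trend on the RPKM with a pseudocount of 0.1, and each library left out. Leaving out each library for the list means was chosen after the data were seen. A gene that changed sign but was called neither way was counted as unchanged. The wild-type libraries are shared by both comparisons with wild-type, so their overlap was set against simulated groups and against splits of the wild-type animals.

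The steps were tested on simulated counts of 17575 genes. For Dp16 against wild-type edgeR recovered 52% of genes changed 1.5-fold and 72% of genes changed 2-fold, with 6 unchanged genes called. For Dp16^2xIFNRs against Dp16 it recovered 50% and 75%, with 5 unchanged genes called. DESeq2 called 27 unchanged genes among 219 and 25 among 221 in these 2 simulations. In the interaction test 66% of genes changed 4-fold in males were recovered, with 3 unchanged genes called. Folds against a group at 0 used a floor of 3 counts over the group, and such floors and counting intervals cover counting error only. Values of immunoglobulin segments, Serpina1a and other near-identical or overlapping genes are uncertain, since reads can be shared.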

Results

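Kidneys of 18 adult mice aged 17.1 to 18.0 weeks were profiled by polyA RNA sequencing. The animals formed 3 groups of 6, each with 3 males and 3 females. Wild-type animals were C57BL/6J. Dp16 mice, a model of trisomy 21, carry an extra copy of the part of mouse chromosome 16 that runs from Lipi to Zbtb21 and corresponds to much of human chromosome 21. Dp16^2xIFNRs mice carry the same duplication with the interferon receptor genes within it brought back to the usual copy number. Library totals ranged from 42157790 to 57814587 gene counts. Xist, the X inactivation transcript, had 880 to 2728 counts in the libraries labelled female and at most 5 in those labelled male. Ddx3y, a Y-linked gene, had 0 counts in every library labelled female and 1339 to 2090 in those labelled male. Of 55385 genes, 17575 passed the filter on low counts. Sex was the largest measured difference, with 3347 genes higher in males and 3466 higher in females, and it was a covariate in every comparison between groups.

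The comparison of Dp16 with wild-type asks what the extra segment does to kidney expression. The 4 interferon receptor genes, which lie at 91372783 to 91565623 on chromosome 16 (GRCm38), were all higher in Dp16. Ifnar2, a subunit of the type I interferon receptor, rose by 0.80 ± 0.05 (log2 fold ± SE, n = 6 per group, edgeR adjusted p = 5.49e-08). Ifngr2, of the interferon gamma receptor, rose by 0.76 ± 0.07, and Il10rb, a shared chain of the interleukin-10 and type III interferon receptors, by 0.605 ± 0.07. Ifnar1, the partner of Ifnar2, rose by 0.58 ± 0.08 (edgeR adjusted p = 0.000185). The mean log2 CPM of the 4 genes was 0.68 higher (95% interval 0.62 to 0.75, exact two-sided permutation p = 0.005, n = 6 per group), in 6 of 6 Dp16 animals. That p is the smallest the 400 permutations within sex can give.

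The rest of the segment rose by nearly as much. Its median log2 fold over 111 tested genes without the receptors was 0.52 (quartiles 0.42 and 0.66), and 3 copies over 2 would give 0.585. The mean log2 CPM of the segment was 0.55 higher in Dp16 (95% interval 0.50 to 0.61, exact permutation p = 0.005, n = 6 per group). Of the 111 genes 67 rose and 0 fell, or 86 and 0 when adjusted over the list alone. App, the amyloid precursor gene, rose from 1570 ± 112.5 to 2347 ± 235 CPM (mean ± SD, n = 6 per group), a log2 fold of 0.58 ± 0.05 (edgeR adjusted p = 1.8e-06). The protease gene Tmprss2 rose by 0.61 ± 0.05, the chaperonin gene Cct8 by 0.58 ± 0.05 and the nucleosome-binding gene Hmgn1 by 0.50 ± 0.05. The highest-expressed segment genes that missed the threshold were Kcnj15 (log2 fold 0.29, adjusted p = 0.0684), Slc5a3 (0.45, adjusted p = 0.0769) and Son (0.27, adjusted p = 0.0585). On chromosome 16 outside the segment, 432 genes had a median log2 fold of -0.01.

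**Figure D1:**
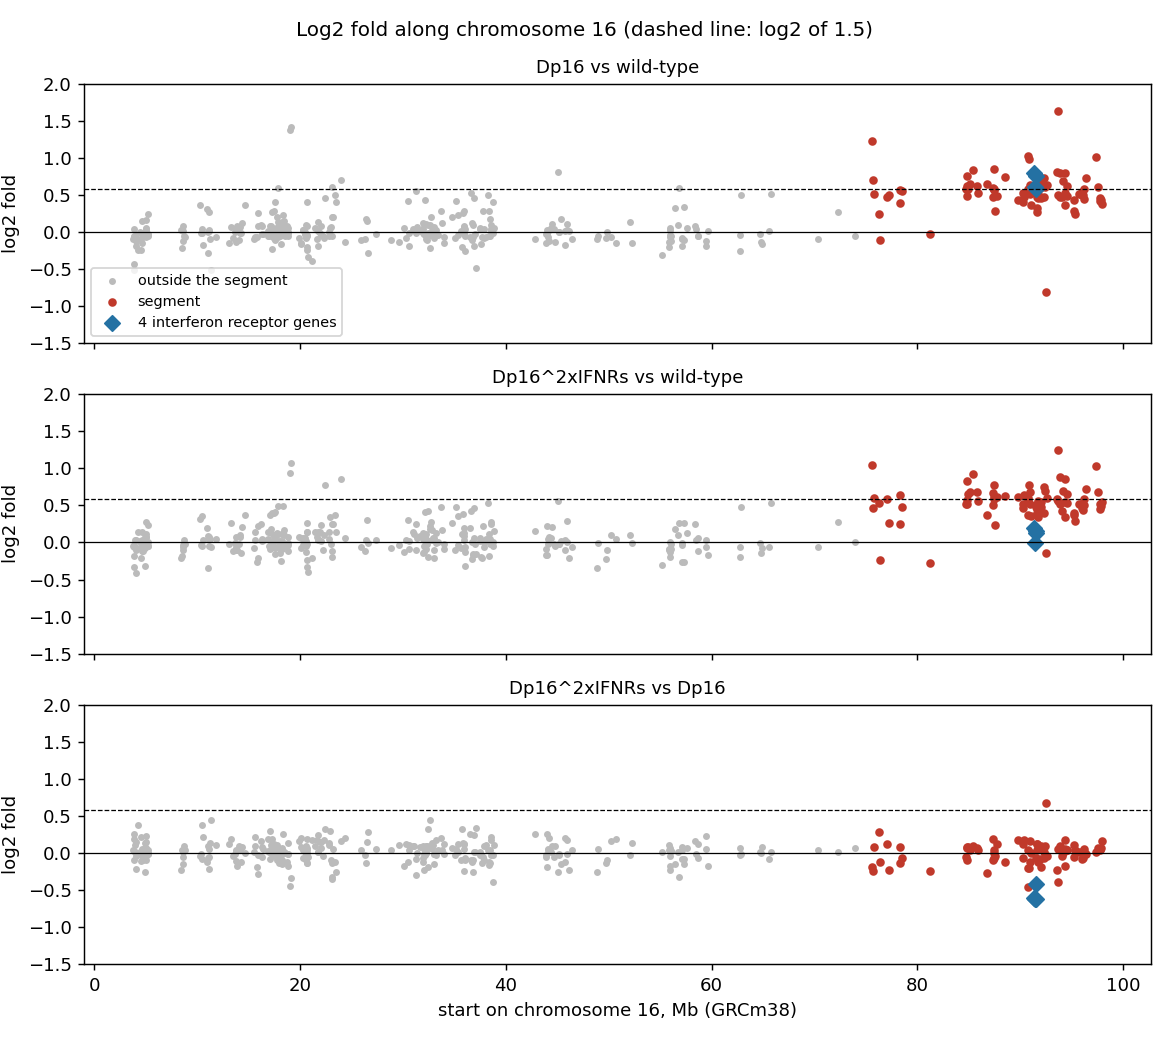
Log2 fold of each tested gene with an average log2 CPM of at least 1 against its start on chromosome 16 in megabases (GRCm38), in 3 panels for the 3 comparisons, with the segment in red, the 4 interferon receptor genes as blue diamonds and all other genes in grey. The dashed line marks 0.585, and the receptor genes sit with the segment in Dp16 against wild-type and near 0 in Dp16^2xIFNRs against wild-type.

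Outside the segment, 487 genes rose and 186 fell in Dp16. Markers of blood-derived immune cells were prominent among the rises. Of 25 macrophage and dendritic cell markers 13 rose and 0 fell, or 22 and 0 adjusted over the list alone (camera adjusted p = 6.51e-26, adjusted p = 0.023 with an estimated correlation). Lyz2, a lysozyme of macrophages, rose by 1.11 ± 0.13 (n = 6 per group, edgeR adjusted p = 5.16e-05) and in 6 of 6 animals, Ms4a7 by 1.18 ± 0.19 and the pore-forming gene Mpeg1 by 0.64 ± 0.10. The list mean was 0.60 higher (95% interval 0.34 to 0.855, exact permutation p = 0.005, n = 6 per group). Of 38 lymphocyte markers 11 rose and 0 fell, or 25 and 0 adjusted over the list alone, with a median log2 fold of 0.89 (camera adjusted p = 8.49e-18, adjusted p = 0.038 with an estimated correlation). Cd4, the helper T cell coreceptor, rose by 1.12 ± 0.21, the T cell receptor gene Trac by 1.103 ± 0.21 and the immunoglobulin light chain gene Igkc by 1.67 ± 0.32. Among genes outside the duplicated segment with an average log2 CPM of at least 0, the largest rise was that of Igkv4-72, an immunoglobulin kappa variable segment, at 3.45 ± 0.70. Variable segments resemble each other closely, so the share of reads counted to each is uncertain. Of 9 neutrophil markers 3 rose and 0 fell, the same numbers adjusted over the list alone, among them the receptor gene Csf3r at 1.29 ± 0.27 (camera adjusted p = 0.000215, adjusted p = 0.066 with an estimated correlation).

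Interferon response genes rose in the same animals. Over 128 genes of the type I and interferon gamma response lists outside the segment the median log2 fold was 0.27, with 32 higher and 0 lower, or 50 and 0 adjusted over the list alone. The mean log2 CPM of these genes was 0.28 higher (95% interval 0.13 to 0.39, exact permutation p = 0.005, n = 6 per group), in 6 of 6 Dp16 animals. The camera p of the joint list was 1.31e-18, and 0.015 with an estimated correlation. The type I list was higher by camera (adjusted p = 7.82e-16, adjusted p = 0.023 with an estimated correlation), with 16 genes up, or 29 adjusted over the list alone. The gamma list had 16 genes up, or 23 adjusted over the list alone, but its camera adjusted p of 3.2e-12 became an adjusted p of 0.19 with an estimated correlation. Lgals3bp rose by 0.61 ± 0.095 (edgeR adjusted p = 0.000891, n = 6 per group), Uba7, the activating enzyme for the ubiquitin-like protein ISG15, by 0.64 ± 0.11 and the transcription factor gene Irf7 by 0.55 ± 0.11. In the gamma list Cd74 rose by 0.59 ± 0.10, H2-Eb1 by 0.61 ± 0.10 and H2-Aa by 0.58 ± 0.11, and Dp16 replicate 3 lay apart above its group in all 3. No gene of these lists is among the immune cell markers above, whose means moved with them. With the macrophage mean as a covariate the interferon difference in Dp16 was 0.018, without a bounded interval, so the rise cannot be told apart from macrophage content.

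Markers of kidney injury and of the tissue around the tubules were also higher in Dp16. Of 26 injury genes 8 rose and 0 fell, or 14 and 0 adjusted over the list alone (camera adjusted p = 7.7e-14, adjusted p = 0.023 with an estimated correlation). Lcn2, a secreted marker of tubule injury, rose by 1.04 ± 0.15 (n = 6 per group, edgeR adjusted p = 0.000377), Lgals3 by 0.48 ± 0.085 and Spp1, osteopontin, by 0.43 ± 0.08. Of 24 complement genes 7 rose and 1 fell, or 12 and 1 adjusted over the list alone, among them C1qb at 0.57 ± 0.10 and C1qc at 0.65 ± 0.12 (camera adjusted p = 1.15e-08, adjusted p = 0.066 with an estimated correlation). Of 33 stroma and fibrosis genes 9 rose and 0 fell, or 23 and 0 adjusted over the list alone, with the matrix gene Mgp at 1.04 ± 0.17 (camera adjusted p = 3.46e-16, adjusted p = 0.092 with an estimated correlation). Of 22 endothelium markers 2 rose and 0 fell, or 9 and 0 adjusted over the list alone (camera adjusted p = 2.05e-05, adjusted p = 0.19 with an estimated correlation), and the list mean was higher in 6 of 6 animals. The p53 and cell cycle exit list was higher (camera adjusted p = 0.00019, adjusted p = 0.038 with an estimated correlation), with 3 of 22 genes up, or 4 adjusted over the list alone. Cdkn1a, the inhibitor p21, rose by 1.05 ± 0.195. The list of inflammatory genes downstream of NF-kappaB had 2 of 28 genes up, or 11 adjusted over the list alone (camera adjusted p = 1.35e-08, adjusted p = 0.023 with an estimated correlation).

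Proximal tubule genes moved the other way. Of 35 markers 6 fell and 1 rose, or 9 and 2 adjusted over the list alone (camera adjusted p = 0.000322, adjusted p = 0.1 with an estimated correlation), and the list mean was lower in 6 of 6 Dp16 animals. The organic anion transporter gene Slc22a8 had a log2 fold of -0.42 ± 0.09 (edgeR adjusted p = 0.0109, n = 6 per group) and the drug-metabolising gene Fmo1 one of -0.425 ± 0.06. Bhmt, which remethylates homocysteine, had a log2 fold of -1.735 ± 0.21 (edgeR adjusted p = 7.53e-05) and was lower in 6 of 6 animals. Serpina1a, one of several near-identical antitrypsin genes whose counts are uncertain, was at -1.52 ± 0.34. The list of the distal and connecting tubule was higher by camera (adjusted p = 0.0118, adjusted p = 0.4 with an estimated correlation), with 1 of 18 genes up, or 2 adjusted over the list alone, and its mean was higher in 5 of 6 animals. Loop of Henle, collecting duct and podocyte lists had camera adjusted p of 0.874, 0.857 and 0.371. In the podocyte list, whose median was -0.02 and whose camera direction was up, Cdkn1c rose by 0.47 ± 0.06.

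In all, 744 genes changed in Dp16, 558 higher and 186 lower (edgeR, adjusted p under 0.05), against 3004 at an unadjusted p under 0.05. The count was 1236 with DESeq2, 190 without the sex covariate and 453 in a fit of the 2 groups alone. It was 429 without Dp16 replicate 3, 462 without Dp16 replicate 1 and 478 without wild-type replicate 4.

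The comparison of Dp16^2xIFNRs with wild-type asks what the segment does when the receptor genes are at their usual dose. The segment without the receptors had a median log2 fold of 0.53 (quartiles 0.42 and 0.68), with 70 of 111 genes up and 0 down, or 83 and 0 adjusted over the list alone. Its mean log2 CPM was 0.55 higher (95% interval 0.50 to 0.61, exact permutation p = 0.005, n = 6 per group). App rose by 0.655 ± 0.05, Tmprss2 by 0.68 ± 0.05 and the purine synthesis gene Gart by 0.51 ± 0.05. Gm5678, at 93628097 to 93630451, had 240 counts against 3 in wild-type, a ratio of 83.6 with a counting interval of 28.3 to 408. The mean log2 CPM of the 4 receptor genes was 0.12 higher than in wild-type (95% interval 0.07 to 0.17, exact permutation p = 0.005, n = 6 per group), and exact permutation p = 0.12 without the sex covariate. Ifnar2 rose by 0.20 ± 0.05 (edgeR adjusted p = 0.0368), a call lost in 13 of 28 alternatives with adjusted p up to 0.28, while Ifngr2 (log2 fold 0.13, adjusted p = 0.333), Ifnar1 (0.16, adjusted p = 0.288) and Il10rb (-0.01, adjusted p = 0.951) did not pass.

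**Figure D2:**
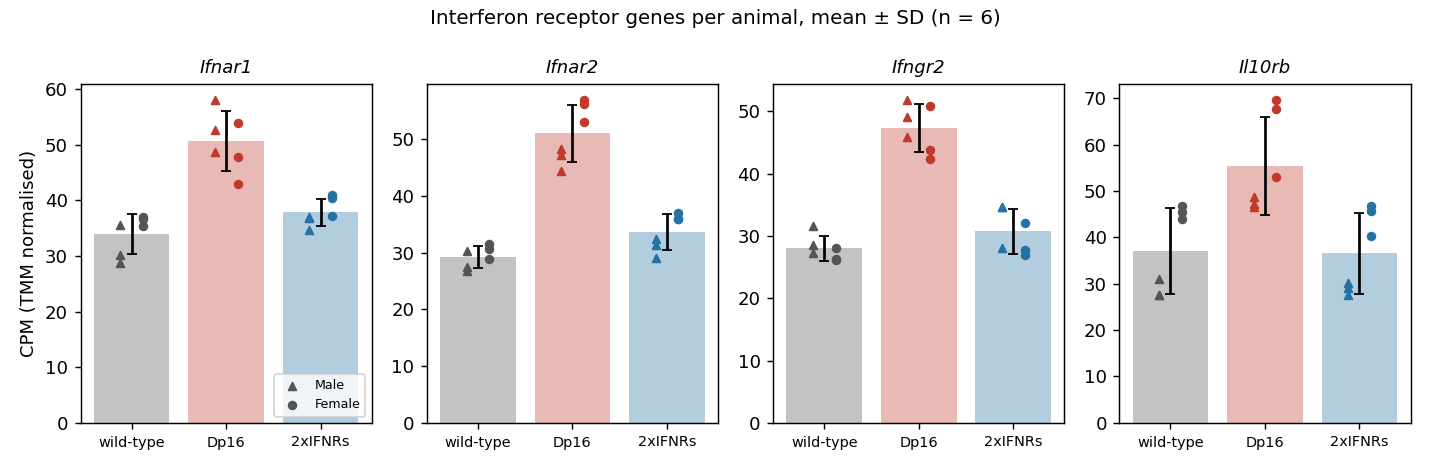
TMM-normalised CPM of Ifnar1, Ifnar2, Ifngr2 and Il10rb per animal, with triangles for males, circles for females, bars for the group mean and error bars for the SD (n = 6). For Ifnar2 the Dp16 animals lie between 44.4 and 56.9 and the Dp16^2xIFNRs animals between 29.1 and 37.0.

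Outside the segment, 487 genes rose and 283 fell in Dp16^2xIFNRs. Of 25 macrophage and dendritic cell markers 18 rose and 0 fell, or 20 and 0 adjusted over the list alone (camera adjusted p = 4.29e-26, adjusted p = 0.061 with an estimated correlation). Their mean was 0.62 higher (95% interval 0.36 to 0.88, exact permutation p = 0.005, n = 6 per group). Lyz2 rose by 1.02 ± 0.13 (n = 6 per group, edgeR adjusted p = 0.000131), Ms4a7 by 1.18 ± 0.19 and Mpeg1 by 0.675 ± 0.10. Of 38 lymphocyte markers 5 rose and 0 fell, or 14 and 0 adjusted over the list alone, including Cd4 at 1.08 ± 0.21 (camera adjusted p = 2.48e-07, adjusted p = 0.21 with an estimated correlation). Dp16^2xIFNRs replicate 1 lay apart above its group in the mean of this list, whose difference ran from 0.48 to 0.668 with 1 library left out. The neutrophil list had 3 of 9 genes up, also adjusted over the list alone (camera adjusted p = 0.000915, adjusted p = 0.13 with an estimated correlation). The 128 interferon response genes had a median log2 fold of 0.25, with 16 higher and 0 lower, or 37 and 1 adjusted over the list alone. Their mean was 0.27 higher (95% interval 0.11 to 0.41, exact permutation p = 0.015, n = 6 per group), in 6 of 6 animals, and camera gave p = 8.22e-15, or p = 0.0287 with an estimated correlation. The p values of the joint list are not adjusted over the lists. Taken apart and adjusted over the lists, neither list held with an estimated correlation. Unadjusted, the camera p with an estimated correlation was 0.007 for the type I list and 0.0904 for the gamma list. The type I list, with 7 genes up, or 10 adjusted over the list alone, went from a camera adjusted p of 9.57e-12 to an adjusted p of 0.063. The gamma list, with 9 up, or 20 up and 1 down adjusted over the list alone, went from 4.41e-10 to an adjusted p of 0.27. Lgals3bp rose by 0.59 ± 0.095, Uba7 by 0.51 ± 0.11 and Cd74 by 0.53 ± 0.10.

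**Figure D3:**
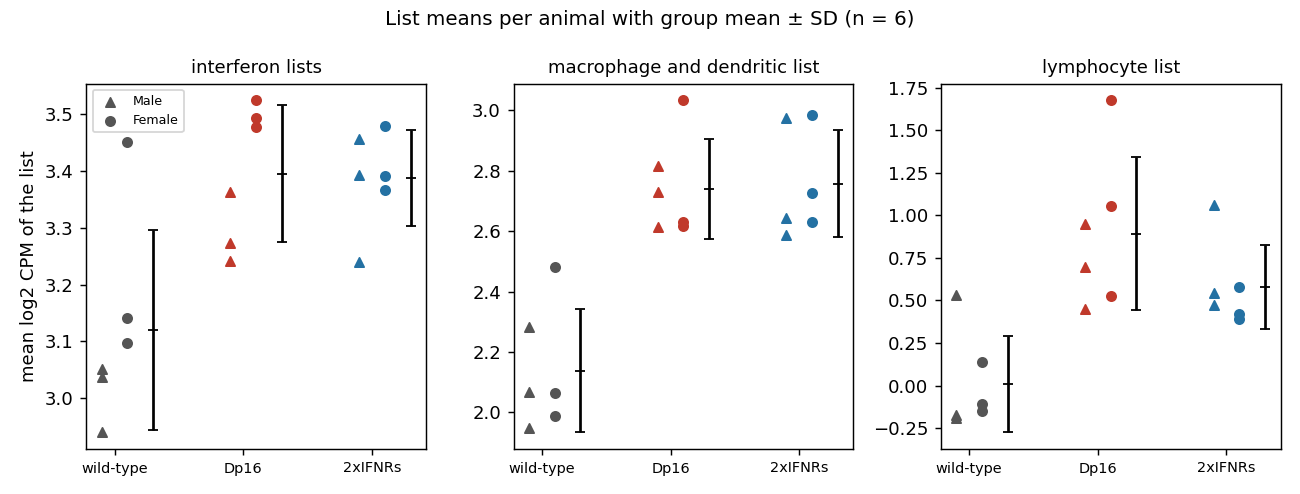
Mean log2 CPM of the interferon response lists, the macrophage and dendritic cell list and the lymphocyte list per animal, with triangles for males and circles for females and the group mean ± SD (n = 6) beside the points. The macrophage mean was 2.14 ± 0.205 in wild-type, 2.74 ± 0.16 in Dp16 and 2.76 ± 0.18 in Dp16^2xIFNRs.

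Injury genes were higher here too, while the stroma list passed camera but not the adjusted permutation test. Of 26 injury genes 8 rose and 0 fell, or 16 and 0 adjusted over the list alone (camera adjusted p = 1.03e-10, adjusted p = 0.061 with an estimated correlation). Lcn2 rose by 0.84 ± 0.15 (n = 6 per group, edgeR adjusted p = 0.00247) and the keratin gene Krt18 by 0.47 ± 0.09. Of 24 complement genes 8 rose, or 10 adjusted over the list alone (camera adjusted p = 4.9e-08, adjusted p = 0.11 with an estimated correlation). Of 33 stroma genes 7 rose, or 15 adjusted over the list alone, among them Mgp at 0.93 ± 0.17 (camera adjusted p = 1.03e-10, adjusted p = 0.21 with an estimated correlation). The stroma mean was 0.29 higher (95% interval 0.08 to 0.48, exact permutation p = 0.03, adjusted p = 0.083 over the lists), in 5 of 6 animals. Of 22 endothelium markers 1 rose, or 10 adjusted over the list alone (camera adjusted p = 1.56e-05, adjusted p = 0.21 with an estimated correlation), and the list mean was higher in 6 of 6 animals. Of 35 proximal tubule markers 7 fell and 1 rose, or 9 and 3 adjusted over the list alone (camera adjusted p = 0.0259, adjusted p = 0.31 with an estimated correlation). The proximal tubule mean differed by -0.05 (exact permutation p = 0.26, adjusted p = 0.35 over the lists) and was lower in 4 of 6 animals. Of 18 distal and connecting tubule markers 2 rose and 0 fell, or 7 and 0 adjusted over the list alone (camera adjusted p = 4.82e-05, adjusted p = 0.19 with an estimated correlation). Their mean was 0.22 higher (95% interval 0.10 to 0.34, exact permutation p = 0.01, adjusted p = 0.036 over the lists, n = 6 per group), in 6 of 6 animals. With 1 library left out that adjusted p reached 0.072 and was under 0.05 without wild-type replicate 2, 4 or 5 or Dp16^2xIFNRs replicate 3 alone. Of 19 podocyte markers 4 rose and 0 fell, or 6 and 2 adjusted over the list alone (camera adjusted p = 0.0335, adjusted p = 0.49 with an estimated correlation). Pck1, the rate-limiting enzyme of gluconeogenesis, had a log2 fold of -1.29 ± 0.21 (edgeR adjusted p = 0.00139), while the sulfate transporter gene Slc13a1 rose by 0.48 ± 0.10. Bhmt was at -1.98 ± 0.21 and Serpina1a at -2.18 ± 0.34. Ribosomal protein genes had a median of -0.14, and all 78 had log2 folds below 0 (camera adjusted p = 2.13e-11, adjusted p = 0.49 with an estimated correlation).

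Lists of adrenal and fat markers did not pass camera here, though single members were called. The adrenal list had 1 of 6 genes lower, or 2 adjusted over the list alone (camera adjusted p = 0.0645, adjusted p = 0.31 with an estimated correlation). Its mean differed by -0.78 (95% interval -1.64 to -0.15, exact permutation p = 0.01, adjusted p = 0.036 over the lists), and by -0.43 without wild-type replicate 5, the highest. With 1 library left out the adjusted p reached 0.15 and was under 0.05 without wild-type replicate 2, 4, 5 or 6 alone. Star, a gene of steroid synthesis in the adrenal, had a log2 fold of -3.94 ± 1.097 (edgeR adjusted p = 0.044), and reached 28.1 CPM in wild-type replicate 5 and at most 1.09 in the other wild-type animals. That call was lost in 17 of 28 alternatives, among them the one without wild-type replicate 5, with adjusted p up to 0.241. The brown fat genes Ucp1 and Cox8b were at -2.26 ± 0.58 and -1.75 ± 0.30, and the whole adipose list had a camera adjusted p of 0.0784. Without the 2 libraries highest in Star, an alternative chosen after the data were seen, 886 genes changed here and the interferon median was 0.32.

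In all, 841 genes changed in Dp16^2xIFNRs against wild-type, 558 higher and 283 lower (edgeR), with 3196 at an unadjusted p under 0.05. DESeq2 gave 1287 and the fit without the sex covariate 234, and the count was 526 without wild-type replicate 1 and 552 without Dp16^2xIFNRs replicate 1.

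The comparison of Dp16^2xIFNRs with Dp16 asks what the dose of the interferon receptor genes does. Calls in edgeR fell on those genes alone. Ifnar2 had a log2 fold of -0.60 ± 0.05 (n = 6 per group, edgeR adjusted p = 7.5e-06), Ifngr2 of -0.63 ± 0.07 and Il10rb of -0.62 ± 0.07. Ifnar1 was at -0.42 ± 0.08 and did not pass over all genes (adjusted p = 0.113), though all 4 passed adjusted over the list alone. Their mean log2 CPM difference was -0.56 (95% interval -0.65 to -0.49, exact permutation p = 0.005, n = 6 per group), lower in 6 of 6 animals. In edgeR these 3 were the only genes called, and DESeq2 called 4. At an unadjusted p under 0.05 there were 827, where chance gives about 879. Outside the segment 0 genes were called by edgeR, with 816 at an unadjusted p under 0.05 and a smallest adjusted p of 0.85. In simulated counts of this comparison edgeR recovered 50% of genes changed 1.5-fold and 75% of genes changed 2-fold, so other differences can be missed.

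The interferon response genes did not pass a test between these groups. Their median log2 fold was -0.01 over 128 genes, 59 of them above 0. The mean differed by -0.01 (95% interval -0.12 to 0.11, exact permutation p = 0.84, n = 6 per group), and the rise of 0.28 in Dp16 over wild-type lies outside that interval in size. The macrophage mean differed by 0.02 (95% interval -0.23 to 0.26) and the injury mean by -0.02 (95% interval -0.25 to 0.19). The rest of the segment differed by 0.01 (95% interval -0.04 to 0.05, exact permutation p = 0.8, n = 6 per group). Camera called 6 lists here, each with an adjusted p of 0.89 with an estimated correlation. Ribosomal protein genes had a median of -0.10 (camera adjusted p = 1.18e-11, all 78 below 0), adipose genes of -0.28 (1.25e-08), oxidative phosphorylation genes of -0.10 (3.4e-09, 4 of 71 above 0) and lymphocyte markers of -0.345 (3.01e-06). Mitochondrially encoded genes had a median of -0.175 (0.00766) and heat shock genes one of 0.10 (0.0394).

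**Figure D4:**
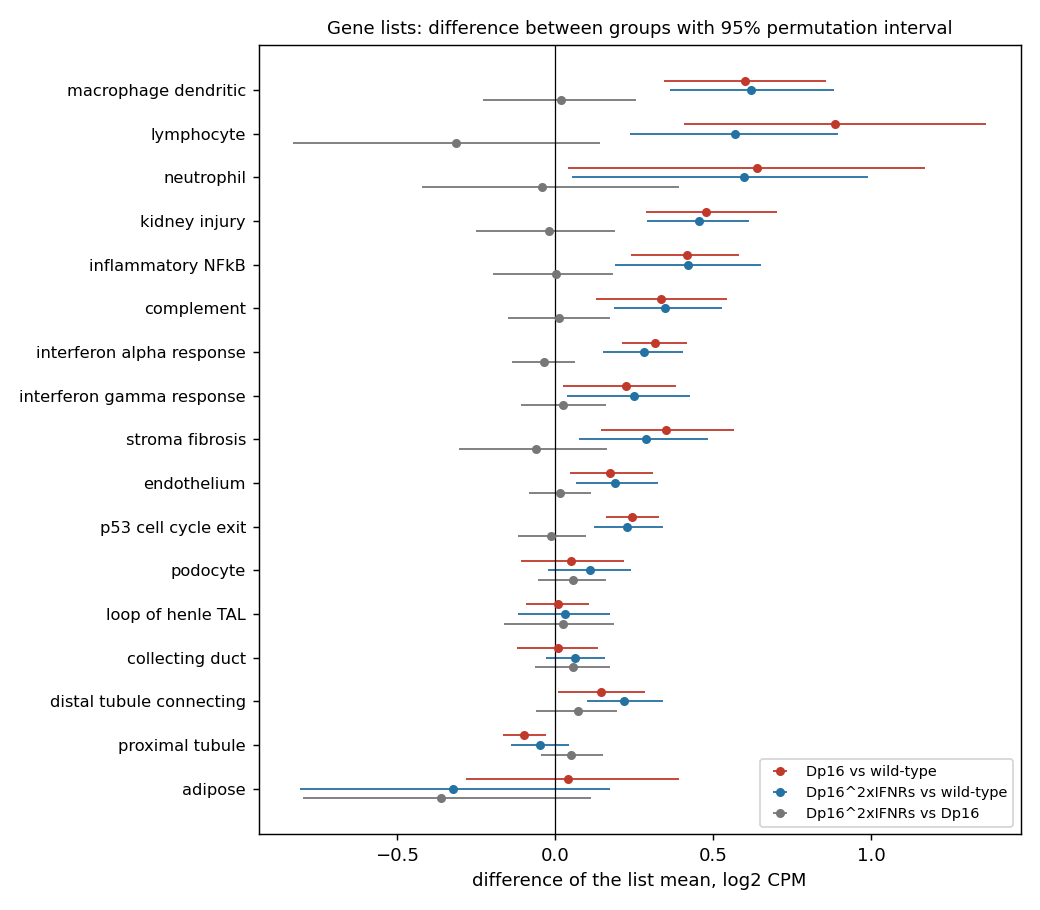
Difference in the mean log2 CPM of each of 17 gene lists with its 95% permutation interval, in red for Dp16 against wild-type, in blue for Dp16^2xIFNRs against wild-type and in grey for Dp16^2xIFNRs against Dp16. The macrophage list lies at 0.60, 0.62 and 0.02 in that order.

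The effects of the 2 duplication-bearing groups against wild-type were compared over 17460 genes outside the segment. Of these, 288 were higher in both and 125 lower in both, against 13.6 and 3 for independent lists, and 0 went opposite ways. The log2 folds correlated across genes, which are not independent replicates, at 0.785. In 20 simulations with no effect the median was 0.497. There all libraries were simulated, gene by gene, and both comparisons shared the simulated wild-type group. The covariance was 0.1103 against 0.0294 in the simulation. With separate sets of 3 wild-type animals for each comparison, the medians over 20 splits were a correlation of 0.449 and a covariance of 0.0822. In these splits a median of 37.5 genes were higher in both and 28 lower in both, against 1.1 and 0.4 for independent lists. The simulated 0.497 holds for a shared wild-type group and is no reference for the 0.449, since separate sets were not simulated.

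The last comparison asks whether the effect of genotype differed between males and females. Prlr, the prolactin receptor gene, at 10177238 to 10349180 on chromosome 15, had the strongest difference. Males had 47.0 ± 21.9 CPM (SD, n = 3) in wild-type, 5.87 ± 1.40 in Dp16 and 5.41 ± 1.51 in Dp16^2xIFNRs, while females had 486 ± 58.9, 476 ± 131 and 425 ± 10.6. The interaction was -2.97 for Dp16 (edgeR adjusted p = 0.00324) and -2.92 for Dp16^2xIFNRs (edgeR adjusted p = 0.00857). The complement gene C2 had an interaction of 0.91 in Dp16 (edgeR adjusted p = 0.0301), with a log2 fold of 0.59 in males and -0.32 in females. For Dp16^2xIFNRs against Dp16, 0 interactions passed in edgeR and 1 by DESeq2. At an unadjusted p under 0.05 there were 676, where chance gives about 879. DESeq2 called 32 and 23 interactions against wild-type where edgeR called 3 and 1. The count for Dp16 was 5 without Dp16 replicate 2 and 14 without Dp16 replicate 3. The count for Dp16^2xIFNRs was 0 without wild-type replicate 6 or Dp16^2xIFNRs replicate 1, 2 without wild-type replicate 2, wild-type replicate 4 or Dp16 replicate 1, and 4, 9 and 3 without Dp16 replicates 2, 3 and 4.

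**Figure D5:**
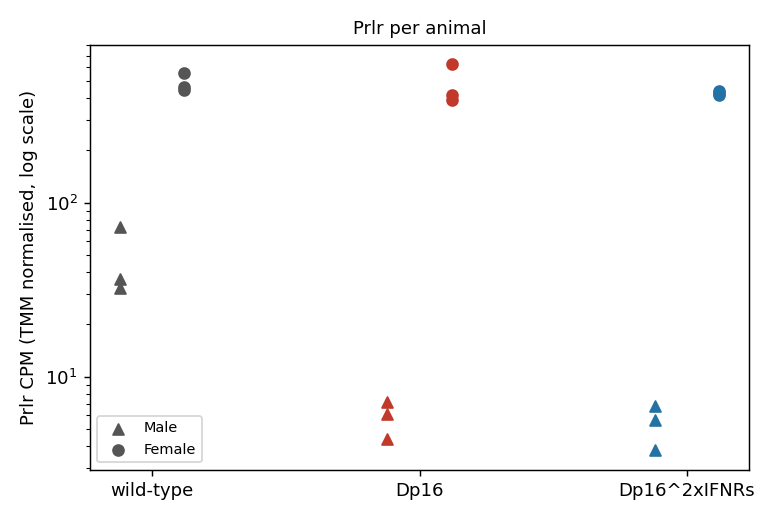
TMM-normalised CPM of Prlr per animal on a logarithmic axis in the 3 groups, with triangles for males and circles for females. Wild-type males lie at 32.15 to 72.15 and males of both other groups at 3.78 to 7.14.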

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

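The set of genes and list means searched for animals apart from their group was drawn up after the comparisons were seen, while the tests of interactions were planned. Values are log2 CPM with the sex difference removed, and an animal counts as apart when its gap to the nearest other animal exceeds the 95% critical value of Dixon's test as a share of the group's range. Of 228 groups of 6 animals searched, 22 had such an animal, where chance gives about 11.4.

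Wild-type replicate 5 stood above its group in Mpeg1 (4.96, others at most 4.5), Lgals3bp (6.86, others at most 6.49), Irf7 (4.22, others at most 3.77) and the interferon list mean (3.37, others at most 3.13). The same animal was highest in Star (4.61, others at most 0.07) and in the adrenal list mean (3.97, others at most 2.43). Wild-type replicate 6 was low in the adipose list mean (3.96, others at least 4.46). Dp16 replicate 1 was high in Star (1.44, others at most -1.03) and in the adrenal list mean (2.9, others at most 1.76).

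Dp16 replicate 3 was high in Cd74 (9.44, others at most 9.16), H2-Eb1 (7.91, others at most 7.6) and H2-Aa (7.78, others at most 7.4), and in Cct8 (7.86, others at most 7.66). Dp16 replicate 4 was low in Il10rb (5.45, others at least 5.8) and Spp1 (9.64, others at least 10).

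Dp16^2xIFNRs replicate 1 was high in Uba7 (3.06, others at most 2.67) and in the lymphocyte list mean (1.07, others at most 0.57). Dp16^2xIFNRs replicate 3 was high in Igkv4-72 (3.23, others at most 0.91) and low in Csf3r (-0.44, others at least 0.47). Dp16^2xIFNRs replicate 4 was low in Cdkn1a (3.14, others at least 4). Dp16^2xIFNRs replicate 6 was low in Ifnar2 (4.96, others at least 5.07) and Cox8b (0.14, others at least 1.52).

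Effects that differed between the sexes included those of Prlr in Dp16 (-2.97, male minus female log2) and Dp16^2xIFNRs (-2.92), and of C2 (0.91) in Dp16.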

How the results depend on the processing

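The segment, receptor and interferon values of both comparisons with wild-type kept their direction and side of the threshold in every alternative, except the receptor mean of Dp16^2xIFNRs, which was 0.118 with exact permutation p = 0.12 without the sex covariate. Where no cause is given below, the cause was not tested. Genes changed numbered 190 and 234 against wild-type without the sex covariate, 1236 and 1287 with DESeq2, and 453 for Dp16 in a fit of 2 groups, which has fewer samples. Of those, 90.5% and 81.6% were higher without the sex covariate, against 75% and 66.3% with it, and 83.6% and 76.8% on the RPKM scale. Without the sex covariate 72 of 159 called values of named genes kept their call, and with DESeq2 158 did. With an estimated correlation 6, 0 and 0 lists were called, and fry called 0 for Dp16^2xIFNRs against Dp16. Interactions numbered 55, 61 and 12 without the filter and 32, 23 and 1 with DESeq2. Between Dp16^2xIFNRs and Dp16 the interferon median turned to 0.001 on the RPKM scale.

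Leaving out 1 library gave 429 to 815 genes for Dp16 against wild-type, 526 to 920 for Dp16^2xIFNRs against wild-type and 3 to 4 between them. Between Dp16^2xIFNRs and Dp16 the segment median ran from -0.015 to 0.034 and the interferon median from -0.055 to 0.006. The segment median was -0.015 without Dp16^2xIFNRs replicate 3, -0.005 without Dp16 replicate 3 and -0.007 without Dp16 replicate 5. The interferon median was 0.004 without Dp16^2xIFNRs replicate 2 and 0.006 without replicate 4. The lowest counts were 429, 462 and 478 without Dp16 replicates 3 and 1 and wild-type replicate 4, and 526 and 552 without wild-type replicate 1 and Dp16^2xIFNRs replicate 1. Lists called between Dp16^2xIFNRs and Dp16 ran from 5 to 10, with 10 without Dp16^2xIFNRs replicate 3 or Dp16 replicate 6. Interactions ran from 2 to 14 for Dp16 (14 and 5 without Dp16 replicates 3 and 2) and from 0 to 9 for Dp16^2xIFNRs (9 without Dp16 replicate 3, and 0 without wild-type replicate 6 or Dp16^2xIFNRs replicate 1). Without the 2 libraries highest in Star, chosen after the data were seen, 512, 886 and 3 genes changed. The adjusted permutation p of list means also missed 0.05 in some of 12 fits without 1 library. In Dp16 these were 8 for lymphocyte and complement, 6 for proximal tubule, 5 for stroma, 2 for injury and 1 each for macrophage and type I interferon lists. In Dp16^2xIFNRs against wild-type they were 7 for lymphocyte, 5 each for macrophage and type I interferon, and 4 each for injury and complement.

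The sample numbers were tried as a replicate block with sex and gave 910, 945 and 3 genes and 16, 22 and 6 lists. The numbers did not pair the animals: same-number residuals correlated at a median of 0.006, against -0.011 for other pairs, and 2 of the 6 numbers held animals of 1 sex. At this depth and spread, simulated genes changed 1.5-fold were recovered in 52% of cases for Dp16 against wild-type, so smaller changes can be missed.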

Other observations

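The tests on tubule share, list means without 1 library, fat, lymph node genes, receptor dose and the coat colour gene were chosen only after the results were seen. Outside the immune and injury groups, Cyp51, a gene of cholesterol synthesis, had a log2 fold of -0.52 ± 0.09 in both Dp16 and Dp16^2xIFNRs against wild-type (edgeR adjusted p = 0.00322 and 0.00274, n = 6 per group, lower in 6 of 6 animals of each). The cholesterol synthesis list did not pass (camera adjusted p = 0.091 and 0.348), with 1 and 2 of 25 genes called lower and 11 and 12 of 25 above 0. Ren1, the renin gene, rose by 0.54 ± 0.11 in Dp16 (edgeR adjusted p = 0.00948). Hlf, a clock-controlled transcription factor gene, was at -0.76 ± 0.19 in Dp16 (edgeR adjusted p = 0.0293), a call lost in 8 of 28 alternatives with adjusted p up to 0.142. In Dp16 camera called the circadian clock list lower (adjusted p = 0.0111, 0.34 with an estimated correlation), with 4 of 21 genes above 0. It also called the immediate early list higher (0.0172, 0.4 estimated) and the drug metabolism and transport list lower (0.00294, 0.29 estimated). Time of day and handling were not tested. Hsp90aa1, a cytosolic chaperone gene, rose by 0.48 ± 0.07 in Dp16^2xIFNRs.

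Mouse counterparts of human chromosome 21 genes that lie on chromosomes 10 and 17, outside the segment, did not pass camera as a list (adjusted p = 0.851 in Dp16 and 0.594 in Dp16^2xIFNRs). In Dp16^2xIFNRs the list mean was higher in 6 of 6 animals, by 0.065 (95% interval 0.01 to 0.12, exact permutation p = 0.025, adjusted p = 0.075). That adjusted p was 0.028 without wild-type replicate 5, 0.033 without Dp16^2xIFNRs replicate 3 and 0.15 without Dp16^2xIFNRs replicate 5. Within the list Lrrc3 fell by 1.00 ± 0.10 and Ftcd, an enzyme of histidine breakdown, by 1.13 ± 0.17 in Dp16, and by 0.98 and 1.18 in Dp16^2xIFNRs. Itgb2, a leukocyte integrin gene in the same region of chromosome 10, rose by 0.75 ± 0.13 in Dp16.

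The immune cell lists were higher in both groups that carry the segment, with macrophage means up by 0.60 and 0.62, against 0.35 and 0.29 for stroma, 0.17 and 0.19 for endothelium and 0.05 and 0.11 for podocytes. A lower share of tubule cells as the whole cause is argued against, since the macrophage mean moved by more than the podocyte, endothelium and stroma means (lowest lower bounds of the gap over both groups 0.224, 0.19 and 0.11, exact permutation p = 0.015 adjusted over the 3 lists), while a part stays open. Fat left on the kidney is argued against in Dp16^2xIFNRs, where the adipose upper bound was 0.175, and stays open in Dp16, where it was 0.392. Lymph node tissue stays open, since 8 lymph node genes, 4 of them also in the lymphocyte list, differed by 0.476 and 0.429 with wide intervals. A larger number of immune cells in the kidney may account for the pattern and stays open, as no count of cells was made.

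The interferon lists were higher in Dp16^2xIFNRs although the receptor genes were near the wild-type level. The lower bound of their difference from wild-type was 0.11, which restates the pattern and cannot test a cause. Between Dp16^2xIFNRs and Dp16 the receptor mean differed by -0.56, but the interferon mean by -0.01 (interval -0.12 to 0.11). The interferon rise of 0.28 in Dp16 over wild-type lies outside that interval in size. These values argue against the extra copy of the receptor genes as the whole cause. The receptor mean was still 0.12 above wild-type (interval 0.07 to 0.17), so a part stays open. More macrophages could be the source: with the macrophage mean as a covariate the interferon difference of Dp16^2xIFNRs from wild-type was -0.037. That test could not bound the difference, because group explains most of the macrophage mean, so this stays open.

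Reads of the nonagouti coat colour gene, at 154791402 to 155051012 on chromosome 2, were found in all 12 animals with the segment and in 0 of 6 wild-type animals, at least 60.3-fold higher in Dp16 and at least 60.2-fold higher in Dp16^2xIFNRs. The overlapping gene Raly had log2 folds of 0.086 and 0.06, not called, at an average log2 CPM of 6.76. A steady share of Raly reads counted to nonagouti would therefore appear in wild-type animals too. Wild-type libraries had 0 nonagouti counts, against 14 to 38 per Dp16 library and 17 to 38 per Dp16^2xIFNRs library, which argues against such a share. A rise of Raly reads in segment-carrying animals alone stays open. A rise smaller than the folds of Raly could supply the 0.558 and 0.557 CPM of nonagouti, so the folds cannot decide that part. Coat colour markers in the engineered chromosome may be the source and stay open: Tyr, the tyrosinase gene, had reads in 4 of 12 and 0 of 6 animals (Fisher's exact p = 0.25). A strain variant at the locus was not tested.

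Whether the segment shifts the sex difference of kidney expression was tested on lists of male- and female-biased genes, whose score differed between sexes by 5.99 in wild-type, 6.05 in Dp16 and 5.89 in Dp16^2xIFNRs. The lowest permutation p of the interaction against wild-type was 0.7. The shuffle within sex, which takes no effect in females, bounded the shift on 1 side in each, at -0.59 or above in Dp16 and 0.64 or below in Dp16^2xIFNRs, so a shift the other way is neither shown nor excluded.

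Other splits of the samples, 100 per comparison with the real one included, were fitted in the same way. For genes changed, 1 of 100 splits, the real one, gave as many in each comparison: 744 against a highest other of 646, 841 against 1, and 3 against 1. These counts hold segment genes, whose copy number sets the groups apart. They were 71 in each comparison with wild-type and all 3 between Dp16^2xIFNRs and Dp16. The splits also did not balance sex, so they do not decide whether chance gives the changes outside the segment. For lists called, 21, 10 and 90 of 100 splits gave as many (17, 19 and 6, highest others 24, 25 and 20), so chance is not excluded. For interactions against wild-type, 14 and 9 of 100 gave as many (3 and 1, highest others 2170 and 22), so chance is not excluded either. Between Dp16^2xIFNRs and Dp16 the real count was 0, so all 100 splits had to give as many and nothing about chance follows (highest other 6). The split with 2170 calls set wild-type replicates 1, 3, 5 and 6 with Dp16 replicates 4 and 5 against the rest. Why it gave a count many times the real one was not identified or tested.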
